A study of Mus musculus with 4 samples.

How the data were processed

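Total RNA from the left ventricular free wall of 4 untreated mice was sequenced, 1 library per mouse. Per the labels, 2 mice carried the VSFP2.3 transgene (TG) and 2 were wild type (WT). Replicate 1 of each genotype was a 35-week male and replicate 2 a 19-week female, and all 4 mice had the same parents. VSFP2.3 is a voltage-sensitive fluorescent protein whose energy transfer between a pair of fluorophores follows membrane potential. Per the labels' protocols, libraries were made with the TruSeq Stranded Total RNA kit and sequenced on a HiSeq2000. The strain background was not given in the sources used here.

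The authors deposited a table of raw read counts per Ensembl gene and a second table of the same genes as a normalized signal. Per the submitters' processing notes, the tools used were CASAVA 1.8.2, FastQC 0.10.0, STAR 2.3.0, HTSeq 0.6.1 and DESeq, with genome build mm10. The annotation release and the strand setting of the counting were not given in the sources used here. The deposited normalized signal equalled the counts divided by 1 factor per library, at 1.08 for WT 1, 1.03 for WT 2, 0.917 for TG 1 and 0.987 for TG 2. The tests below used the raw counts as deposited.

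The count table held 38355 genes, of which 1125 had an identifier but no symbol. Gene totals were 15498935 for WT 1, 16762713 for WT 2, 14860759 for TG 1 and 14158440 for TG 2. A count of 0 allows a level of up to 3 counts, or 0.182 to 0.213 counts-per-million units (CPM) depending on the library. Reads carried no molecular identifiers as far as the labels say, so these limits cover counting error only. Positions, biotypes and exonic lengths came from the GENCODE vM21 annotation of the same mouse assembly, matched by Ensembl identifier, and 99.2% of the tested genes had a match. Mitochondrially encoded genes were not analysed here.

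Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 14189 genes, and library sizes were scaled by trimmed means (TMM; factors of 1.06 for WT 1, 0.934 for WT 2, 0.947 for TG 1 and 1.06 for TG 2). TG was compared with WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05, without a block. The 35-week males were compared with the 19-week females in the same way, as a second difference present in the same libraries. Sex and age could not be separated, since each male was 35 weeks old and each female 19 weeks. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. CPM values use TMM-scaled library sizes, and log2 ratios within a pair use a prior count of 2. Standard errors (SE) are those of the fitted log2 fold changes. With 2 mice per genotype, p-values describe the spread among these 4 animals.

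A further test asked whether the TG to WT ratio differed between the male and the female pair. It was added after the values per library were seen. A model with genotype, pair and their interaction leaves no residual degrees of freedom with 4 libraries, so the interaction was the only term fitted, which leaves 2. The test equals a comparison of WT 1 and TG 2 with WT 2 and TG 1. Its coefficient is 2 times the fitted log2 ratio of WT 2 and TG 1 over WT 1 and TG 2. This equals the log2 TG to WT ratio of the male pair minus that of the female pair only where genotype and pair add no difference of their own.

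The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. There were 33 lists, covering the hypertrophy and fetal programme, sarcomere, calcium handling, cardiac ion channels, intercalated disc, fibrosis and extracellular matrix, inflammation, interferon response, p53 and apoptosis, endoplasmic reticulum stress, heat shock and protein folding, the ubiquitin, proteasome and autophagy genes, oxidative stress, fatty acid oxidation, glycolysis and glucose uptake, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, the circadian clock, cell cycle and sex genes. Marker lists covered endothelium, fibroblasts, smooth muscle and pericytes, macrophages, lymphocytes, neutrophils, erythroid cells, adipocytes, atrium, nerve and Schwann cells, epicardium and mesothelium, and skeletal muscle. Each list of at least 5 tested genes was compared with the other genes by camera, with a preset correlation of 0.01 and with a correlation estimated per list. Fry was run as well, which tests whether the genes of a list change, in one direction or in either, without comparing them with other genes. Both were adjusted by Benjamini-Hochberg over the 30 lists tested.

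For TG against WT, the rule named 16 fixed cardiac genes whatever their values, and genes past the threshold that moved alike in both pairs. Since none passed, the 10 genes of smallest p in each direction that moved alike in both pairs were named, leaving out predicted genes, which numbered 1528 among those tested. For each list the called members were named up to 4, or else the 2 of smallest p. For males against females, the called genes and 5 sex-linked genes were named. The interaction test was given 12 genes per direction. Of the genes so named, 4 are not reported here.

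Same-numbered mice were matched for sex and age per the labels but were different animals. Deviations from the genotype means correlated at r = -0.449 across genes between WT 1 and TG 1, so the matched mice did not deviate together. The fit with the pair as a replicate block was run as an alternative. Other alternatives were DESeq2 size factors, library totals and upper-quartile factors in place of TMM, no filter or a minimum of 1 CPM in 2 libraries, an adjusted p below 0.1, removal of haemoglobin and abundant non-coding genes, and each library left out in turn. The abundant non-coding genes removed were Rmrp, Rpph1 and those with names starting with Rn7s, while Yam1 was kept. Removal of each library's trend on exonic gene length, also for the lists, and a crossed pairing were added later.

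The procedure was tested on counts simulated from the real means and library sizes, with a common spread for all genes. No difference between libraries was put in other than the tested one. For TG against WT, on 13998 genes of which 83, 54 and 63 were changed 1.5-, 2- and 4-fold, edgeR recovered 1.20%, 14.8% and 76.2% of them, with 3 false calls. For males against females, on 14018 genes, it recovered 1.64%, 4.23% and 80.9%. For the interaction, on 14027 genes, it recovered 8.96%, 47.1% and 98.5%. There the 1.5-, 2- and 4-fold changes were put in between WT 2 and TG 1 on one side and WT 1 and TG 2 on the other. The matching interaction is 2 times the log2 of such a fold, so these shares do not hold for 1.5-, 2- and 4-fold interactions. In a simulated set of 21 lists of 20 genes, camera with the preset correlation called the list raised 2-fold and none of the unchanged lists. With an estimated correlation camera gave the raised list an adjusted p of 0.381, so that setting had little power in this simulation. The simulated genes varied independently, so the check does not cover lists whose genes move together.

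Genes that share sequence with near-identical copies were treated as uncertain, since counting may split their reads. Among those named, these include Atp5g1, Gapdh, Eif1, Tmem14c, Hspa1a and Hspa1b, the haemoglobins, the immunoglobulin and class I histocompatibility genes, and the small nuclear, nucleolar and Y RNAs. Transcripts were compared with BLAST 2.17.0. Without a stated strand setting, genes that overlap a neighbour are uncertain too. Among the named genes the overlap covered 84.2% of the exonic length of Atn1, 61.5% of Nppa, 59.6% of Pln, 45.5% of Gpld1, 33.0% of Phlda1, 21.2% of Psmc3ip and nearly all of Rnu3a and all of Snora73b. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.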

Results

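RNA from the left ventricular free wall of 4 mice was sequenced to ask whether the voltage indicator VSFP2.3, expressed in heart muscle cells, is toxic to the heart, per the purpose the submitters stated. Each of 2 transgenic (TG) and 2 wild-type (WT) mice gave 1 library of 14158440 to 16762713 counted reads, with 18334 to 19001 genes having at least 1 count. WT 1 and TG 1 were 35-week males and WT 2 and TG 2 were 19-week females, all from the same parents. Each sex- and age-matched TG and WT mouse is called a pair below.

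Counts of sex-linked genes matched the labelled sex of all 4 mice. Ddx3y, on the Y chromosome, had 3289 and 2699 counts in the males and 0 in both females. Xist, the RNA that silences an X chromosome in females, had 4915 and 3815 counts in the females and 3 and 14 in the males. Transcripts of the transgene were not analysed here, so the genotype labels were not checked by a targeted gene. Myh6, the adult cardiac myosin whose promoter commonly drives such transgenes, was measured at 22820 ± 6301 CPM in WT and 26625 ± 7765 in TG (SD, n = 2).

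WT 2 differed from the other libraries in make-up. Its protein-coding genes took 89.9% of counts, against 96.7 to 97.4% in the others. The non-coding gene Yam1 held 685444 counts, or 4.09% of WT 2, against 7376 in WT 1, 2094 in TG 1 and 2626 in TG 2. Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, held 137304 counts in WT 2 against 314 to 780 in the others. Myl4, the atrial essential myosin light chain, was at 75.6 CPM in WT 2 and at 0.711 to 1.16 CPM in the other 3.

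Between TG and WT hearts, none of 15 fixed genes of cardiac stress, calcium handling, conduction and matrix passed the test, and their log2 fold changes lay between -0.36 and 0.56. The natriuretic peptide genes Nppa and Nppb, which cardiomyocytes raise under load, had log2 fold changes (TG over WT, ± SE, 2 mice per genotype throughout) of 0.28 ± 0.73 and -0.12 ± 0.41. The fetal myosin Myh7 was at 0.02 ± 0.21, Myh6 at 0.22 ± 0.29 and skeletal actin Acta1 at -0.33 ± 0.39. The calcium-handling genes Atp2a2 (the sarcoplasmic reticulum pump), Pln (its inhibitor) and Ryr2 (the release channel) were at 0.25 ± 0.15, 0.04 ± 0.15 and 0.22 ± 0.36. The channel and gap junction genes Kcnj2 and Gja1 were at 0.11 ± 0.14 and -0.12 ± 0.28. The matrix genes Col1a1, Col3a1 and Postn were at 0.56 ± 0.24, -0.36 ± 0.37 and -0.19 ± 0.31, and the stress-response genes Ddit3 and Hspa5 at -0.23 ± 0.23 and 0.08 ± 0.17. Each of these 15 genes had an adjusted p of 1.00 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The signs of 12 of them turned when 1 library was left out, so no direction is read from them, and the overlap of Nppa and Pln with other genes on the opposite strand leaves their levels uncertain.

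**Figure D1:**
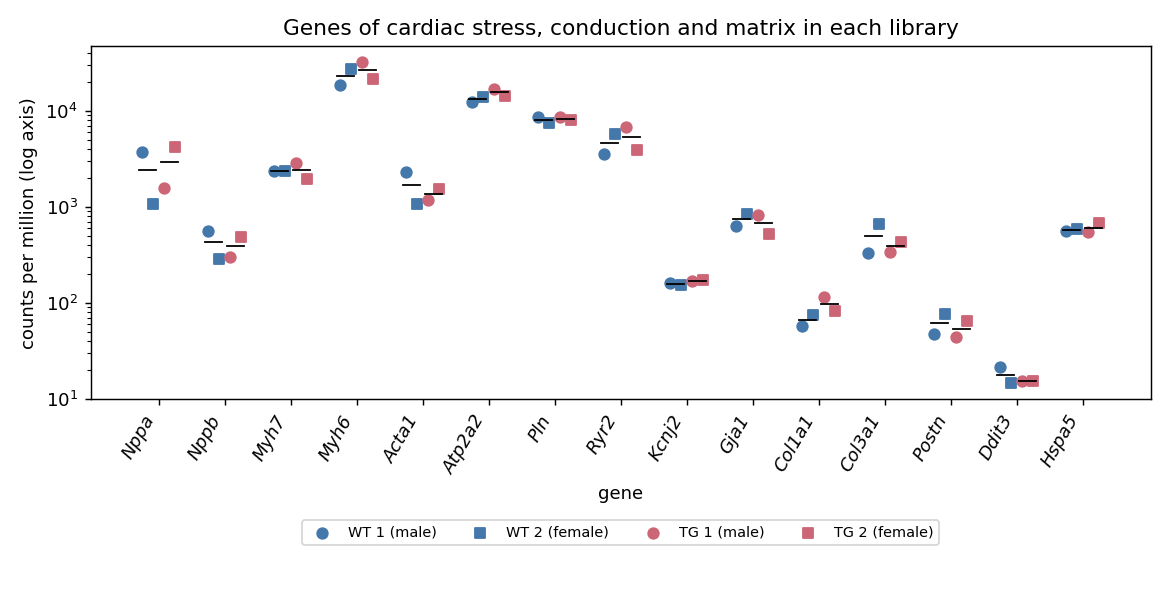
Counts-per-million values (CPM, log axis) of 15 cardiac stress, conduction and matrix genes in each library. Blue marks WT, red TG, circles the 35-week males, squares the 19-week females, and black lines the genotype means. The ranges of WT and TG overlap for each gene except Atp2a2, Col1a1 and Kcnj2, and Nppa runs from 1057 CPM in WT 2 to 4228 in TG 2.

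Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14189 genes between TG and WT, with a smallest adjusted p of 1.00. Unadjusted p-values below 0.05 were found for 99 genes, where chance alone would give 709. Genotype held 12.8% of the between-library variance of log2 CPM and the pair 23.9%. The split of WT 1 and TG 2 from WT 2 and TG 1 held 63.3%. The test counts these latter shares as spread within genotypes, so few small p-values are not evidence that the genotypes are alike. Limma-voom also called 0 genes, with 95 below an unadjusted 0.05, and DESeq2 called 3. These were Atp5g1, Psmc3ip and the predicted gene Gm11814, with adjusted p-values of 1.43e-07, 0.0106 and 1.44e-05 by DESeq2, and Gm11814 is named after its values were seen. With the pair as a replicate block, edgeR and DESeq2 both called 0 (61 and 47 below an unadjusted 0.05). Without WT 1, edgeR called 8 genes, all lower in TG. In counts simulated with a common spread for all genes, 76.2% of 4-fold changes were recovered but 14.8% of 2-fold changes. The real libraries held further differences. Psmc3ip (4.69-fold higher in TG) and Gm11814 (4.48-fold) were not called by edgeR, so 4-fold changes may have been missed more often than in the simulation.

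The genes of smallest p that moved alike in both pairs did not pass the edgeR test, and their values follow. Atp5g1 (ENSMUSG00000006057, chromosome 11, 96068852 to 96075670, in the mm10 assembly), which encodes subunit c of the mitochondrial ATP synthase, was at 36.4 ± 0.326 CPM in WT and 11.5 ± 0.703 in TG (SD, n = 2), a log2 fold change of -1.66 ± 0.14. Its processed copy Gm10039, 99.8% identical over 411 bp, held 4879 and 4409 counts in WT and 4694 and 5065 in TG. In CPM these were 297 and 282 in WT and 334 and 336 in TG, higher in TG in both pairs, so the value of Atp5g1 is uncertain. Psmc3ip (ENSMUSG00000019303, chromosome 11, 101091823 to 101095436), a cofactor of meiotic recombination, was at 1.65 ± 0.249 CPM in WT and 7.76 ± 0.0856 in TG, a log2 fold change of 2.23 ± 0.28. It overlaps the gene Mlx on the opposite strand over 21.2% of its exonic length, so its value is uncertain. Gm11814, a processed pseudogene, was at 3.21 ± 0.159 CPM in WT and 14.4 ± 1.33 in TG. Its transcript is 92.2% identical to Ldha over 638 bp. Ldha was at 406 and 410 CPM in WT and 355 and 375 in TG, lower in TG in both pairs, so the value of Gm11814 is uncertain too.

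Other genes with higher values in TG were the inward-rectifier channel gene Kcnj14 (1.36 ± 0.28), the cationic amino acid transporter Slc7a1 (0.72 ± 0.16), the scaffold gene Ush1c (2.52 ± 0.58), the retinoic acid hydroxylase Cyp26b1 (1.57 ± 0.37), Rgmb (0.58 ± 0.16), the hypoxia-inducible factor Epas1 (0.85 ± 0.24), Phlda1 (0.89 ± 0.26), Camk2n1 (0.54 ± 0.16) and the histone demethylase Kdm6b (0.84 ± 0.25). Those with lower values were the thin-filament gene Neb (-0.85 ± 0.14), Trim68 (-1.41 ± 0.24), the myosin-binding protein Mybpc2 (-0.68 ± 0.17), Tmem86a (-0.56 ± 0.15) and the glycine cleavage gene Gcsh (-0.49 ± 0.14). The small RNA genes with lower values were the Y RNA Rny3 (-0.84 ± 0.20), Rnu3a (-1.47 ± 0.36), Rnu12 (-2.46 ± 0.69) and Snora73b (-0.59 ± 0.17). Each had an adjusted p of 1.00 by edgeR with Benjamini-Hochberg adjustment. Kcnj14, Ush1c, Mybpc2 and Tmem86a lie within 2.55 Mb of chromosome 7 (44501699 to 47054777), a stretch singled out after the positions were seen. Of 80 tested genes there, 7 had an unadjusted p below 0.05 by edgeR, against 0.698% of all tested genes. The genes that singled out the stretch are among these 7. Hrc and Kcnj11, named with the lists below, lie there too.

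Among the gene lists, haemoglobin and other erythroid genes, interferon response genes and intercalated disc genes stood apart from the other genes between TG and WT. All 6 of 6 erythroid genes had lower values in TG, with a median log2 fold change of -1.14 (camera adjusted p = 3.45e-05), for example Hbb-bs at -1.32 ± 0.69 and Hba-a1 at -1.24 ± 0.61. Interferon response genes were lower in 27 of 28, with a median of -0.58 (camera adjusted p = 6.35e-05), for example Stat2 at -0.57 ± 0.28 and Irf7 at -1.54 ± 1.09. Their median was -2.23 in the male pair and 1.33 in the female pair. Intercalated disc genes were higher in 16 of 19, with a median of 0.14 (camera adjusted p = 0.0214), for example Ank2 at 0.52 ± 0.17 and Jup at 0.34 ± 0.18. With an estimated correlation none of the 3 lists was called (adjusted p = 0.998 for each), and fry, which tests a list for change without comparing it with other genes, called 0 lists (smallest adjusted p = 0.993). The estimated correlations were 0.945 for the erythroid, 0.941 for the interferon and 0.538 for the intercalated disc list, against the preset 0.01. No member of any list passed the edgeR test, over all genes or adjusted over the list alone. Without WT 1 the medians of the erythroid and interferon lists were 0.028 and 0.83, and without TG 1 that of the intercalated disc list was -0.071. The log2 fold changes of TG over WT rose with exonic length across protein-coding genes (Spearman's rho 0.228, genes not being independent replicates), and the intercalated disc list had a median of 0.12 with the length trend removed and of 0.13 without a filter, without being called (adjusted p = 0.145 and 0.0560). With the pair as a replicate block, heat shock (adjusted p = 0.0138) and circadian clock genes (adjusted p = 0.0227) were called as well, 5 lists in all.

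The other 27 lists tested were not called without the block, with camera adjusted p-values from 0.0583 to 0.997. In the muscle lists, values were higher in TG for 7 of 17 hypertrophy and fetal programme genes (Rcan1 -0.33 ± 0.29), 11 of 20 sarcomere genes (Des -0.30 ± 0.14, Actn2 0.39 ± 0.30), 13 of 19 calcium-handling genes (Hrc 0.56 ± 0.19, Cacna2d1 0.39 ± 0.14) and 23 of 31 ion channel genes (Kcnj11 -0.54 ± 0.23, Hcn2 0.61 ± 0.29). For skeletal muscle markers the count was 1 of 5 (Casq1 -0.73 ± 0.39, Tnni2 -0.69 ± 0.76), and for atrial markers 5 of 11 (Myl4 -5.36 ± 1.96, Tbx5 0.40 ± 0.15), where the value of Myl4 rests on WT 2. Metabolic lists stood at 16 of 33 for fatty acid oxidation (Acot2 0.60 ± 0.20, Lpl 0.48 ± 0.22), 12 of 27 for glycolysis (Gapdh -1.15 ± 0.49, Pfkfb2 -0.27 ± 0.13) and 10 of 44 for oxidative phosphorylation (Uqcrq -0.28 ± 0.18, Ndufs7 -0.17 ± 0.14). Gapdh was counted at only 4.13 to 13.3 CPM and has many processed copies.

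Stress and signalling lists were also divided. Values were higher in TG for 16 of 26 endoplasmic reticulum stress genes (Trib3 -0.65 ± 0.38, Asns -0.58 ± 0.45), 15 of 26 heat shock genes (Dnajb1 1.04 ± 0.51, Hspa1b 2.3 ± 1.15), 12 of 28 ubiquitin, proteasome and autophagy genes (Stub1 -0.23 ± 0.15, Psmb1 -0.15 ± 0.15), 14 of 30 oxidative stress genes (Sod3 0.20 ± 0.16, Gpx3 -0.22 ± 0.20) and 15 of 28 p53 and apoptosis genes (Sesn2 0.50 ± 0.26, Bcl2 0.46 ± 0.33). Hspa1b stood at 18.0 CPM in TG 1 and at 1.15 to 2.80 CPM in the other libraries. The counts were 14 of 25 for inflammation (Tnf -1.45 ± 0.57, Ptgs2 0.63 ± 0.45), 18 of 27 for immediate early genes (Gadd45g -1.12 ± 0.45, Klf4 0.61 ± 0.31), 13 of 20 for the circadian clock (Per1 1.24 ± 0.49, Cry2 0.45 ± 0.24), 5 of 19 for the cell cycle (Cenpf 0.82 ± 0.50, Cdk1 -0.62 ± 0.50) and 4 of 9 for sex genes (Ddx3x 0.10 ± 0.28, Kdm5c -0.08 ± 0.49).

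Matrix and cell-type lists were higher in TG for 11 of 30 matrix genes (Thbs1 -0.66 ± 0.20), 8 of 18 fibroblast markers (Fbln1 0.41 ± 0.20, Pdgfra 0.27 ± 0.14), 8 of 20 endothelial markers (Erg 0.55 ± 0.23, Egfl7 -0.58 ± 0.30), 5 of 16 smooth muscle and pericyte markers (Tagln -0.48 ± 0.26), 6 of 14 adipocyte markers (Pnpla3 -0.90 ± 0.49, Scd1 0.39 ± 0.24) and 8 of 12 nerve and Schwann cell markers (Ncam1 0.35 ± 0.26, Gfra3 -0.52 ± 0.42). They were higher for 2 of 22 macrophage markers (Cd163 -1.05 ± 0.47) and 9 of 17 lymphocyte markers (Igj 2.12 ± 2.11, Ighm 0.93 ± 0.94). Too few neutrophil and epicardial markers were measured for a test, with 2 of 3 and 2 of 4 higher in TG (S100a9 -0.48 ± 1.21, Mmp9 0.20 ± 0.50, Wt1 0.56 ± 0.32, Krt18 -1.0 ± 0.84), and mitochondrially encoded genes were not analysed here. Median, mean and test differed in sign for the inflammation, lymphocyte, endothelial, fibroblast, endoplasmic reticulum stress, oxidative stress, fatty acid oxidation, nerve and sex gene lists.

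Within the pairs, TG and WT hearts differed strongly and in opposite directions. The median log2 TG to WT ratios of the macrophage, lymphocyte and interferon response lists were -1.76, -3.70 and -2.23 in the 35-week males, against 1.36, 3.08 and 1.33 in the 19-week females. Cd74, the invariant chain of class II histocompatibility molecules, was at 573 and 497 CPM in WT 1 and TG 2 against 45.2 and 35.1 in WT 2 and TG 1. The light chain of class I molecules, B2m, was at 979 and 915 CPM in WT 1 and TG 2 against 188 and 177 in WT 2 and TG 1, and the pan-leukocyte gene Ptprc at 73.4 and 60.3 CPM in WT 1 and TG 2 against 11.6 and 9.53 in WT 2 and TG 1. The natriuretic peptide genes followed the same split, with Nppa at 3707 and 4228 CPM in WT 1 and TG 2 against 1057 and 1556 in WT 2 and TG 1 and Nppb at 564 and 482 CPM in WT 1 and TG 2 against 283 and 299 in WT 2 and TG 1. A test of the difference between the pairs, added after these values were seen, called 386 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 336 with a lower TG to WT ratio in the males and 50 with a higher one. DESeq2 called 703 (218 higher, 485 lower) and limma-voom 261 (33 higher, 228 lower).

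Since the interaction was the only term fitted, the test equals a comparison of WT 1 and TG 2 with WT 2 and TG 1. The number called was 44 without WT 1, 110 without TG 2, 274 without WT 2 and 366 without TG 1, of which 36, 95, 198 and 225 were among the 386. Splitting the 4 libraries by genotype called 0 genes and splitting them by pair called 4.

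**Figure D2:**
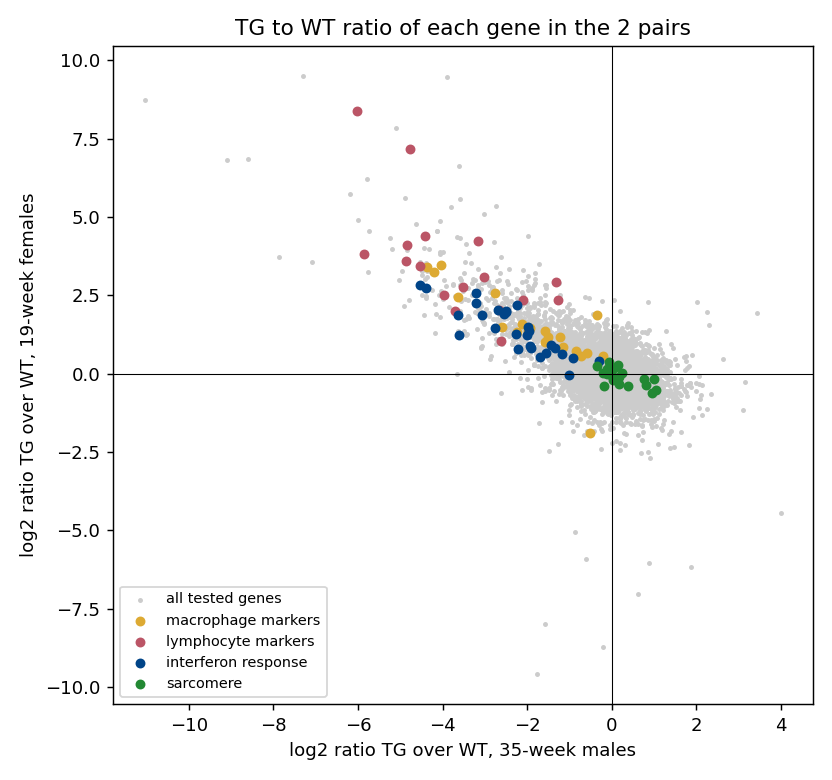
Log2 ratio of TG over WT for each of 14189 tested genes in the 35-week male pair (horizontal) and the 19-week female pair (vertical), 1 library per genotype in each. Grey points are all genes and coloured points members of 4 lists. Pearson's r across genes is -0.66, and lymphocyte, macrophage and interferon response genes lie at the upper left, lower in TG than WT in males and higher in females.

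Among the fixed lists, lymphocyte, macrophage, interferon response and inflammation genes held most of the calls. Of lymphocyte markers 12 of 17 were called (17 adjusted over the list alone), all with a lower TG to WT ratio in males. The T-cell receptor gene Cd3e was at 4.62 and 4.25 CPM in WT 1 and TG 2 against 0.512 and 0.285 in WT 2 and TG 1, and Lck, Cd3g and Nkg7 were at 5.65 and 6.51 against 0.256 and 0.0711, 5.78 and 6.11 against 0.384 and 0.0711 and 4.20 and 3.98 against 0.0640 and 0.0711 in the same order. Several of these values lay near the limit of a 0 count in WT 2 and TG 1, so no fold is given. Of macrophage markers 14 of 22 were called (21 adjusted over the list alone), with class II genes H2-Aa and H2-Ab1 at 374 and 270 against 28.6 and 20.1 and 214 and 159 against 15.0 and 10.3 and the lysosomal protease Ctss at 89.3 and 68.6 against 11.5 and 13.2. The scavenger receptor Cd163 did not follow, at 22.7 and 5.98 against 22.6 and 16.0. Of interferon response genes 13 of 28 were called (26 adjusted over the list alone), among them the immunoproteasome subunits Psmb8 and Psmb9 at 98.7 and 66.8 against 14 and 10.5 and 39.9 and 30.3 against 8.0 and 6.76, and Gbp3 at 75.4 and 44.8 against 7.36 and 8.04. Of inflammation genes 7 of 25 were called (17 adjusted over the list alone), among them the chemokines Ccl8 at 26.7 and 28.0 against 0.448 and 0.782, Ccl5 at 4.20 and 4.85 against 0.320 and 0.0711 and Cxcl16 at 29.6 and 22.2 against 8.83 and 10.2, and Il1b at 6.75 and 5.58 against 0.384 and 0.285.

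Further called members were the proliferation genes Mki67 (-2.92 ± 0.37, fitted interaction on the log2 scale ± SE, 2 times the log2 ratio of WT 2 and TG 1 over WT 1 and TG 2) and Top2a (-3.07 ± 0.53) of the cell cycle list, Casp12 (-4.26 ± 0.38) of the apoptosis list, Socs3 (-2.21 ± 0.37) of the immediate early list and the mitochondrial carrier Ucp2 (-2.36 ± 0.34) of the oxidative stress list. Nppa (-3.21 ± 0.42, adjusted p = 0.0224) and Nppb (-1.69 ± 0.25, adjusted p = 0.0319) were the called members of the hypertrophy list by edgeR with Benjamini-Hochberg adjustment, and Nppa also of the atrial list. Without WT 1 their fitted interactions were -3.39 and -1.46 and did not pass (adjusted p = 0.153 and 0.267 by edgeR with Benjamini-Hochberg adjustment), nor did those of -3.01 and -1.91 without TG 2 (adjusted p = 0.138 and 0.113) or of -1.61 for Nppb without WT 2 (adjusted p = 0.0626). With the length trend removed they were -2.47 and -0.92 (adjusted p = 0.0641 and 0.122). Vwf (1.41 ± 0.23) of the endothelial list and Notch3 (1.53 ± 0.22) of the smooth muscle list went the other way. Camera with the preset correlation called 10 lists. The lymphocyte, macrophage, interferon, inflammation, immediate early, apoptosis and cell cycle lists had lower ratios in the males, and the intercalated disc, circadian clock and glycolysis lists higher ones. Without WT 1 the glycolysis, circadian clock and cell cycle lists were not called (adjusted p = 0.117, 0.142 and 0.0613), nor was glycolysis without WT 2 (0.132) or the circadian clock without TG 1 (0.202). With the length trend removed the intercalated disc and circadian clock lists had medians of 0.51 and 0.46 (0.63 and 0.38 before, where the median of all genes moved from 0.01 to 0.18) and were not called (adjusted p = 0.0503 and 0.10). With an estimated correlation none was called (smallest adjusted p = 0.118), and with library totals in place of TMM the median of the glycolysis list was -0.067 instead of 0.29, where that of all genes was -0.34 instead of 0.01 and the list was still called (adjusted p = 0.0461). Adjusted over the list alone, 112 members of 19 lists were called, while fry called 3 for one direction and 7 for change in either direction. Median, mean and test differed in sign for the calcium-handling, heat shock, adipocyte and skeletal muscle lists, none of them called. Erythroid genes, which mark blood, had negative medians in both pairs, at -1.47 in males and -0.26 in females.

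**Figure D3:**
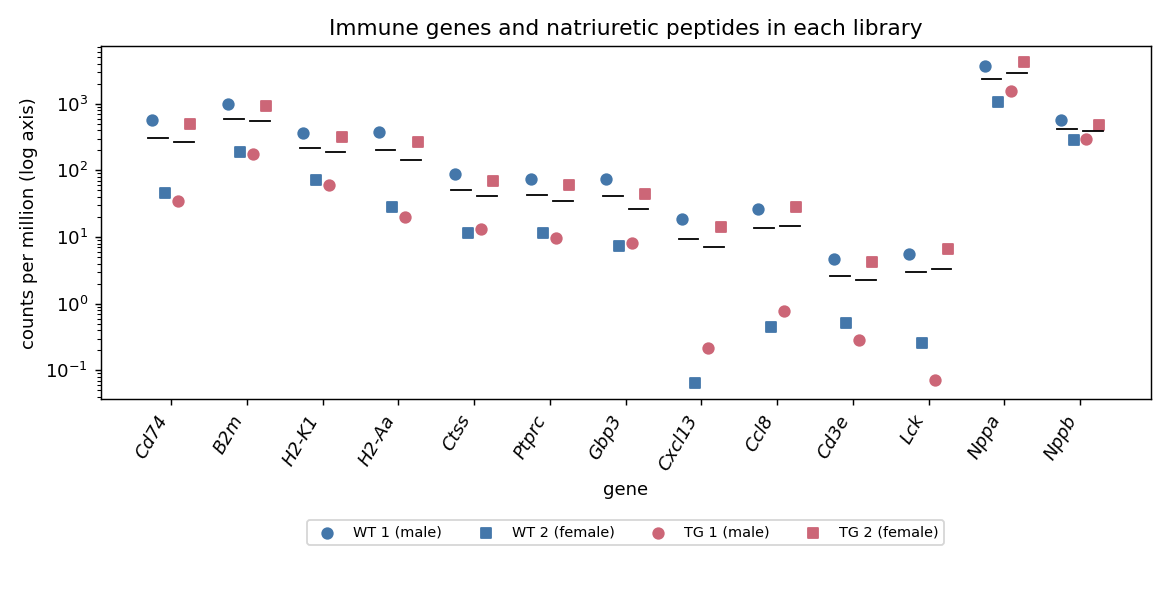
Counts-per-million values (CPM, log axis) of 11 immune genes and the natriuretic peptide genes in each library, with black lines at the genotype means. Blue marks WT, red TG, circles the 35-week males and squares the 19-week females. WT 1 and TG 2 lie above WT 2 and TG 1 for each gene, as for Cd74 at 573 and 497 CPM against 45.2 and 35.1.

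The 12 named genes of smallest p with a lower TG to WT ratio in males were Ccl8, Cd74, B2m, the class I gene H2-K1, the B-cell chemokine Cxcl13, Ifi27, H2-Ab1, Ptprc, Ctss, the leukocyte GTPase Rac2, H2-Aa and Cyfip2. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.00492 to 0.00575. H2-K1 was at 360 and 321 CPM in WT 1 and TG 2 against 70.8 and 60.2 in WT 2 and TG 1, and Cyfip2 had a fitted interaction of -3.60 ± 0.24. The 11 given with a higher ratio in males were Tmem14c, Eif1, Efnb3, Lrp1, Hspg2, Stard9, Atn1, Gpld1, Uso1, Zfp609 and Mccc1, with adjusted p-values from 0.0129 to 0.0301. Hspg2, which encodes the basement membrane proteoglycan perlecan, was at 416 and 486 CPM in WT 1 and TG 2 against 898 and 931 in WT 2 and TG 1, and the lipoprotein receptor Lrp1 at 280 and 306 CPM in WT 1 and TG 2 against 549 and 563 in WT 2 and TG 1. Tmem14c (2.74 ± 0.28) and Eif1 (2.20 ± 0.24) share sequence with copies, and Atn1, Gpld1 and Stard9 overlap other genes, so their values are uncertain. Genes with a higher ratio in males numbered 0 among those called without WT 1 and 1 without TG 2.

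Long genes took part in the split in the direction opposite to the immune genes. The 50 genes with a higher ratio in males had a median exonic length of 8752.5 bp, against 3445.5 bp for 312 protein-coding genes with a lower ratio and 4597 bp for all protein-coding genes tested. Ttn, the longest sarcomere gene, was at 61652 and 63260 CPM in WT 1 and TG 2 against 96929 and 118161 in WT 2 and TG 1 (fitted interaction 1.57 ± 0.29, adjusted p = 0.0570 by edgeR with Benjamini-Hochberg adjustment, not passing). Over 12736 protein-coding genes outside the immune lists, Spearman's rho between the fitted interaction and exonic length was 0.280, where genes are not independent replicates. Removal of each library's length trend left 320 genes called, 302 of them among the 386.

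**Figure D4:**
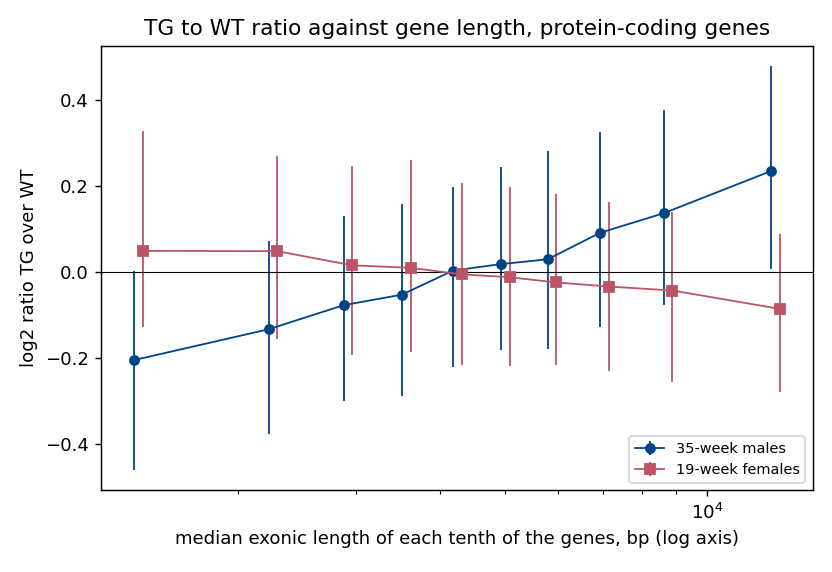
Median log2 ratio of TG over WT in 10 equal groups of protein-coding genes ordered by exonic length (bp, log axis), for the 35-week males and the 19-week females, 1 library per genotype in each. Bars run from the 25th to the 75th percentile over genes. The ratio rises with length in the male pair and falls in the female pair.

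The 35-week males and 19-week females differed clearly in Y-linked genes. Ddx3y, Eif2s3y, Uty and Kdm5d were the 4 genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p from 0.0215 to 0.0397), with 513 genes below an unadjusted 0.05. They had 0 counts in both females, and their mean levels in males were 1002, 351, 297 and 148 times the limit of 3 counts per female library, 0.196 CPM. As far as counting error goes, the males were higher than the females by at least these folds. Xist was 482-fold higher in the females and did not pass (adjusted p = 0.147). DESeq2 called 34 genes, 20 higher and 14 lower in males, with an adjusted p left undefined for 1376 genes, and limma-voom called 4. With a genotype term, edgeR called 0 (229 below an unadjusted 0.05) and DESeq2 7. The count was 0 without WT 1, WT 2 or TG 1 (605, 256 and 471 below an unadjusted 0.05) and 9 without TG 2.

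Of the lists, camera with the preset correlation called 11 between males and females, a test added after the data were examined. Values were higher in males for 6 of 6 erythroid genes (median 1.48), 27 of 28 interferon response genes (0.58), 12 of 17 hypertrophy genes (0.16) and 19 of 27 immediate early genes (0.16). The sex genes were called as well, where the median (-0.54 with 4 of 9 higher in males) and the test differed in sign. Values were lower in males for 11 of 14 adipocyte (-0.35), 13 of 18 fibroblast (-0.24), 26 of 33 fatty acid oxidation (-0.14), 22 of 30 matrix (-0.23), 8 of 11 atrial (-0.44) and 15 of 20 endothelial genes (-0.08). The interferon response list stood highest in WT 1, with median log2 CPM values of 4.99 in WT 1 and 2.57 in TG 1 against 2.47 in WT 2 and 3.88 in TG 2, so that the males lay on both sides of TG 2. Atrial markers include Myl4, which was high in WT 2. Erythroid genes stood highest in WT 1, with median log2 CPM values of 5.71 against 4.63 in TG 1, 4.27 in WT 2 and 4.22 in TG 2. With an estimated correlation none was called (smallest adjusted p = 0.477), and fry called 1 list for one direction and 3 for either. With a genotype term the interferon list was not called (adjusted p = 0.0511) and the heat shock list was (0.00627). Sex and age cannot be separated in these mice.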

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

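The test of the difference between the pairs was chosen only after the result was seen, as were the tests of blood, of libraries exchanged between or within pairs, of a few genes taking most of the counts, and of the length trend on the called long genes; the tests of the length trend on the immune genes and on all long genes were set before their results were seen.

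The TG to WT ratio of 386 genes differed between the male and the female pair, lower in the males for 336 and higher for 50. What drew attention was a difference between groups under the same contrast, by an interaction test whose only term splits WT 1 and TG 2 from WT 2 and TG 1. Values below are the fitted interactions, 2 times the log2 ratio of WT 2 and TG 1 over WT 1 and TG 2. Fitted values of genes near a 0 count in WT 2 and TG 1, such as Cxcl13 (-13.71) and Ccl8 (-10.95), depend on the prior count. The others with lower ratios in males were Ccl8 (-10.95), Cd74 (-7.47), B2m (-4.75), H2-K1 (-4.75), Ifi27 (-3.76), H2-Ab1 (-7.76), Ptprc (-5.31), Ctss (-5.36), Rac2 (-5.66), H2-Aa (-7.45) and Cyfip2 (-3.60). Nppa (-3.21) and Nppb (-1.69) followed them. Higher ratios in males were found for Tmem14c (2.74), Eif1 (2.20), Efnb3 (2.49), Lrp1 (1.85), Hspg2 (2.04), Stard9 (1.91), Atn1 (2.59), Gpld1 (2.28), Uso1 (1.62), Zfp609 (1.85) and Mccc1 (2.12).

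Immune genes were higher in WT 1 and TG 2 than in WT 2 and TG 1. In the female pair, blood left in the tissue is argued against, since the erythroid median was -0.26 (SD over members 0.235, 5 of 6 below 0) while the macrophage median was 1.36. Erythroid genes moved together (estimated correlation 0.945 in the TG against WT fit) and each genotype of the pair is 1 library. The SD over members therefore does not measure how far mice vary, and the values speak for these 2 libraries only. In the male pair the erythroid median was -1.47, in the direction of the immune lists, so a part played by blood stays open there. A trend on gene length is argued against. Its removal left the 39 called macrophage, lymphocyte and interferon members at a median absolute interaction of 4.99 (5.36 before), with 34 still called. Those members were picked by the same test. Over all tested members of these lists, which were fixed beforehand, the medians were -2.46, -6.96 and -3.60 after removal. Before removal they were -3.19, -7.45 and -3.69. An exchange of libraries between the pairs is argued against by the Y-linked and Xist counts, which matched the labelled sex in all 4 libraries. Genotype labels exchanged within one pair may also give this pattern and cannot be told apart from a true difference, because 0 genes of the table name the transgene or a fluorescent protein and the genes that ran with the labels in both pairs, such as Atp5g1 (-1.72 and -1.58), Psmc3ip (2.02 and 2.29) and Gm11814 (2.26 and 1.98), were picked for doing so and are not known to follow the transgene. Biological differences that the design names, sex and age, and the state of each single mouse also stay open and untested, since each genotype of each pair is 1 animal.

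Long genes differed between the pairs in the direction opposite to the immune genes, mostly through the male pair. There the median log2 TG to WT ratio was -0.20 in the shortest and 0.23 in the longest 10% of protein-coding genes outside the immune lists. In the female pair these medians were 0.044 and -0.086. A few genes taking most of the counts is argued against, since 1 factor per library moves genes of all lengths alike, while the medians of the longest and shortest 10% of protein-coding genes differed by 0.57 on the log2 scale (SD over resampled genes 0.03). A test set earlier, leaving out the 10 most abundant genes, kept 99.9% of the median of the longest genes but decided nothing, because TMM already trims such genes. A trend on gene length between libraries is consistent with the values over all genes (Spearman's rho 0.280, with 0.346 in the upper and 0.205 in the lower part of the expression range), and its source, such as RNA quality, was not tested. For the 50 called genes, the median after removal of the trend was 1.62 (1.71 before, while the median of all genes moved from 0.01 to 0.18), and 32 were still called. These genes were picked for high values by the same test, so this cannot decide whether the trend was the whole cause. A biological difference between the mice stays open and untested.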

How the results depend on the processing

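The interaction test with all its settings, the removal of the length trend, the crossed pairing and the lists of males against females were chosen only after the data were seen, while the other alternatives were set beforehand. Leaving out a library leaves 1 library in an arm, and that lone sample is assumed to vary like the others. Causes were not tested except where the setting itself shows them. With 2 mice per genotype, 2-fold changes between TG and WT were mostly not detectable at this spread.

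For TG against WT, the count of called genes was 0 with each scaling, filter and threshold tried, with limma-voom and with the pair as a replicate block in edgeR or DESeq2, and 3 with DESeq2 without the block. It ran from 0 to 8 with a library left out, 8 being without WT 1. The number of lists called, 3, was 0 with an estimated correlation and by fry for one or either direction, 5 with the replicate block, with or without sex genes, 2 without a filter or with the length trend removed (the intercalated disc not being called in either, with medians of 0.13 and 0.12 against 0.14), 2 with haemoglobin and abundant non-coding genes left out, 4 with library totals or upper-quartile factors, and 6 to 13 with a library left out (6 without TG 1, 8 without TG 2, 10 without WT 1, 13 without WT 2). Apart from these lists and the genes of DESeq2, the block changed no call between TG and WT. The setting without abundant non-coding genes kept Yam1. Same-numbered mice did not deviate together (r = -0.449), and with the pairing crossed edgeR called 0 genes and DESeq2 5.

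Of the 15 fixed genes, 12 turned sign with a library left out, none having passed the test. Their ranges of log2 fold change were -0.61 to 1.45 for Nppa, -0.53 to 0.47 for Nppb, -0.27 to 0.26 for Myh7, -0.11 to 0.54 for Myh6, -0.77 to 0.32 for Acta1, -0.066 to 0.16 for Pln, -0.22 to 0.61 for Ryr2, -0.48 to 0.17 for Gja1, -0.78 to 0.24 for Col3a1, -0.50 to 0.19 for Postn, -0.48 to 0.072 for Ddit3 and -0.090 to 0.23 for Hspa5. The medians of the lists ran from -0.071 to 0.35 for the intercalated disc, from -1.54 to 0.83 for the interferon response and from -1.76 to 0.028 for erythroid genes. Myh7 also turned sign with upper-quartile factors (-0.00018), limma-voom (-0.0079), the length trend removed (-0.031), the replicate block (-0.0084), the block in DESeq2 (-0.0054), the block without sex genes (-0.0083) and the crossed pairing (-0.0084). Nppb was 0.024 with the length trend removed.

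For males against females, the 4 calls became 34 with DESeq2, 7 without a filter and 0 with a genotype term, and ran from 0 (without WT 1, WT 2 or TG 1) to 9 (without TG 2). The 4 Y-linked genes were called with each other setting that kept all libraries. Xist passed with library totals, without a filter and with DESeq2.

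For the difference between the pairs, the 386 calls became 703 with DESeq2, 908 without a filter and 698 at an adjusted p below 0.1, and ran from 44 to 366 with a library left out. All 12 named genes with lower ratios in males and 0 of the 11 with higher ratios stayed called without each library in turn, and none of them turned sign. Library totals shifted the median of all genes to -0.34 from 0.01 and gave 15 genes with higher and 464 with lower ratios, and removal of the length trend shifted it to 0.18. Nppa and Nppb were not called with the length trend removed (-2.47 ± 0.47 and -0.92 ± 0.23, against -3.21 ± 0.42 and -1.69 ± 0.25 before), and Stard9 was lost as well (1.36). The 10 lists called became 0 with an estimated correlation, 3 by fry for one direction and 16 without a filter, were 9 with the length trend removed, and the glycolysis median was -0.067 with library totals, still above that of all genes.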

Other observations

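The genes and pairs of values in this part were chosen after their values were seen, as were the tests of Atp5g1's copies and of a single chromosome segment; the test of neighbouring genes was set before its result was seen.

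Several more immune genes, some of them members of the lists above, also differed between the pairs. The immunoglobulin gene Ighg1 was at 53.7 and 234 CPM in WT 1 and TG 2 against 0.192 and 0.213 in WT 2 and TG 1, and the joining chain gene Igj at 19.0 and 83.9 CPM in WT 1 and TG 2 against 0.448 and 0.569 in WT 2 and TG 1. The interferon-induced GTPases Igtp, Iigp1 and Irgm2 were at 678 and 286 against 12.1 and 12.7, 794 and 280 against 17.7 and 21.5 and 320 and 146 against 15.0 and 15.3 CPM in the same order, and the T-cell genes Cd4 and Cd8a at 4.26 and 7.17 against 0.256 and 0.356 and 7.42 and 3.52 against 0.128 and 0. Each of these passed the interaction test (adjusted p from 0.00972 to 0.0280 by edgeR with Benjamini-Hochberg adjustment). Among macrophage genes, Ccr2 and Emr1 were at 27.8 and 31.3 against 5.63 and 2.13 and 57.5 and 40.1 against 15.8 and 12 (adjusted p = 0.0248 and 0.0209 by edgeR with Benjamini-Hochberg adjustment), and Lyve1 and Timd4 at 19.5 and 22.8 against 15.4 and 16.9 and 5.59 and 3.59 against 2.17 and 2.77 (adjusted p = 0.294 and 0.246, not passing). Other genes were chosen because their values lay apart between males and females. Col14a1 was at 26.7 and 25.2 CPM in the males against 105 and 89.9 in the females, and the complement gene C7, Penk, Cdkn1a and Txnip at 60.7 and 62.5 against 5.18 and 8.57, 14.8 and 17.2 against 3.13 and 2.26, 9.12 and 8.61 against 25.3 and 30.7 and 301 and 320 against 961 and 774. None of these passed the test of males against females by edgeR (adjusted p from 0.159 to 0.435). TG 1 alone had high values of Cenpf, at 162 CPM against 56.9 to 66.2 in the others, and of the heat shock gene Hspa1a, at 12.1 CPM against 0.384 to 2.37.

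A few genes followed the labelled genotype in both pairs, and 4 of the 20 of smallest p, predicted genes included, lay close together on chromosome 7. A hypothesis is that a chromosome segment was inherited with the genotype, as may happen around an insertion site or with mixed strain backgrounds. The test set beforehand left it undecided, since 4 of the 20 genes lay within 5 Mb of another (24.9% of 10000 random draws gave as many), while a test chosen afterwards, the largest number within one stretch of 5 Mb, also gave 4 (0.1% of draws as many, 95th percentile 2). Shared reads between Atp5g1 and its copies cannot be told apart from a true change. The summed counts were higher in TG by only 0.050 and 0.13 on the log2 scale in the male and the female pair. The change of Atp5g1 alone would lower that sum by at most 0.115. The segment may hold variants of one strain that alter expression or read mapping, and whether these follow the transgene was not tested.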
